A study of Mus musculus with 9 samples.

How the data were processed

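RNA from the kidney cortex of 20-week-old male mice on the C57BLKS/J background was measured on 9 Affymetrix arrays, 3 per group, each labelled as a separate biological replicate. The db/m mice carry 1 copy of the leptin receptor mutation and serve as lean controls, and db/db mice lack a working leptin receptor and become obese and diabetic. The third group was db/db mice given Tang-shen Formula (TSF), a Chinese herbal formula, by gavage at 2.4 g/kg/day for 12 weeks, while the other db/db mice received saline. Per the labels, 9 mice were in each of the 2 db/db groups, and 3 arrays per group were used here.

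The deposited values are intensity values, 1 per probe set and array, on a linear scale. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console, and the background correction, normalization and summary settings are not given in the sources used here. The deposited intensity values were all above 1, and the array medians lay between 10.3 and 11.2. On the log2 scale the largest gap between array medians was 0.114. No 2 arrays were copies of each other: pairs of arrays shared identical values at 3 to 70 probe sets. For arrays, the number of arrays limits the precision. No detection calls were used here, so a low intensity cannot be told from background.

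Of 41345 probe sets, 190 were array controls. Probe sets were named through the platform annotation: 23521 had 1 gene symbol, 1814 had several, and 15820 others were not named in it. The Entrez identifiers of 23328 probe sets matched a RefSeq gene table of the GRCm38 mouse assembly, and 0 symbols changed. Only probe sets with 1 symbol were used. They covered 22180 genes, 1082 of them with more than 1 probe set, and the probe set with the highest mean over the 9 arrays stood for its gene. Intensities were transformed as log2(value + 1), so fold changes are on that scale and understate the change of dim genes. Genes whose mean lay under the 30th percentile of all probe sets (2.65 on the log2 scale) were left out, which left 17740 genes. Xist, which fell under the filter, was not tested.

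A linear model with 1 mean per group was fitted to all 9 arrays with limma version 3.58.1 in R version 4.3.3, with eBayes moderation and neither an intensity trend nor robust settings. The arrays were not rescaled, and median scaling and quantile normalization were alternatives. The 3 pairs of groups were compared. The threshold was a Benjamini-Hochberg adjusted p of 0.05. All adjusted p-values of single genes in the text come from this limma fit unless another is named. Standard errors (SE) are those of the moderated fit. In the text a value in parentheses after a gene is its log2 fold change, and a value after an array left out is camera's adjusted p without that array.

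The comparisons and their tests, 43 gene lists of kidney cell types and pathways taken from textbook knowledge, and the rule for named genes were fixed before the data were examined; 963 of their 1069 entries matched a gene with a probe set. The list of red cell markers kept 3 members, under the minimum of 4, and 42 lists were tested with limma's camera at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the 42. Camera with an estimated correlation, camera on ranks and fry, which tests whether the genes of a list move on balance one way, were alternatives. The rule for named genes took, per comparison, the 10 largest rises and falls among genes past the threshold whose groups did not overlap and whose symbols are not clone or model numbers, or, where fewer than 5 passed in a direction, the 5 of smallest p named as not passing. It also took up to 4 members of smallest p from each list past the threshold, up to 2 from other lists, a set of fixed genes (Lepr, Zbtb16, Havcr1, Lcn2, Nphs1, Ucp1 and Xist, and 1 more that is not reported here), and genes past the threshold in opposite directions in db/db against db/m and in db/db+TSF against db/db, of which there were 0. Zbtb16 was on that list because published work on this treatment is known to discuss it. The plan noted that those authors chose it on these samples, so its choice is independent neither of such work nor of these data. Genes named outside the rule, and tests of explanations chosen after results were seen, are said to be so where they appear.

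The relation between the TSF effect and the db/db effect was measured across genes as the covariance of the 2 log2 fold changes. Because both use the same db/db arrays, 100 simulations of unchanged groups gave the covariance that sharing alone produces. Alternatives covered the choice of probe set, the filter, rescaling of arrays, quantile normalization, the variance model, array weights, the arrays in the fit, the replicate number as a block, the pseudocount, the threshold, a test without moderation and leaving out each array in turn. The list and gene tests were tested on simulated data made from the means and spreads of the 17740 genes, in 20 runs with 200 genes changed in db/db against db/m. For a log2 change of 0.5 the test recovered 26.9% of changed genes, for 1 it recovered 91.2% and for 2 it recovered 99.3%. A shift of 0.3 in a list of 20 genes was found in 20 of the 20 runs, with genes simulated as independent, so this does not carry over to lists whose members vary together. Data were prepared with Python version 3.11.15, pandas 2.3.3 and numpy 2.4.6.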

Results

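Kidney cortex expression was compared between lean db/m mice, diabetic db/db mice given saline and db/db mice given Tang-shen Formula (TSF), with 3 arrays per group. The series set out to look for genes through which TSF acts on diabetic kidney injury. Array medians lay between 10.3 and 11.2 intensity units. The first principal component, 32.3% of the variance, placed the 3 db/m arrays on one side and the 6 arrays of db/db and db/db+TSF on the other. The second component, 16.6% of the variance, had db/db replicate 3 at one end and db/db+TSF replicate 2 at the other.

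**Figure D1:**
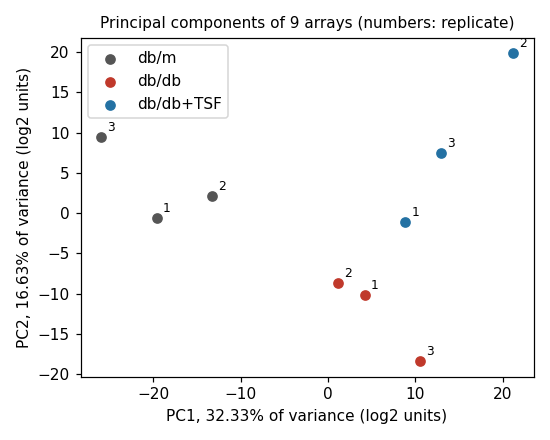
Each point is 1 array, placed by its scores on the first (x) and second (y) principal component of log2 intensities of 17740 genes, coloured by group and numbered by replicate. The db/m arrays lie between -25.97 and -13.27 on the first component and the arrays of db/db and db/db+TSF between 1.18 and 21.16.

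The comparison of db/db with db/m shows how the cortex of obese, diabetic mice differed from that of lean mice. Genes that androgens raise in the male kidney were lower in db/db (adjusted p = 8.2e-12, and adjusted p = 0.124 with an estimated correlation). Slco1a1, an organic anion transporter, fell from 8.36 ± 0.23 to 2.21 ± 0.14 on the log2 scale (SD, n = 3; limma adjusted p = 3.2e-10), and since its db/db values lie near the bottom of the intensity scale the fitted 71.1-fold difference depends on the floor. Cyp7b1, a steroid hydroxylase, was 7.17-fold lower (log2 fold change -2.84, SE 0.39), and Cd36, the fatty acid translocase, was 4.11-fold lower (-2.04, SE 0.29). The monoamine oxidase gene Maob was 2.8-fold higher (1.49, SE 0.15).

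The other genes among the largest falls were Slc22a26 (-3.42), Slc22a7 (-3.25), Alox15 (-3.18), Ugt2b37 (-2.96), Pzp (-2.81), Akr1c14 (-2.37) and Ldc1 (-2.03), which include organic anion transporters of the Slc22 family, a lipoxygenase and a glucuronosyltransferase. The largest rises besides Maob were Sprr1a (1.64), Mtarc1 (1.28), Abcb1b (1.25), Xpnpep2 (1.18), Bbox1 (1.09), Agmo (1.01), Pdk1 (0.99), Cyp17a1 (0.97) and Mpzl2 (0.95). Sprr1a is one of the tubular injury markers, Abcb1b encodes a drug efflux pump and Bbox1 the last enzyme of carnitine synthesis. A second, dimmer probe set of Pdk1 differed by 0.22. Of these 20 genes Slc22a7, Ugt2b37, Pzp, Akr1c14, Sprr1a, Abcb1b and Cyp17a1 did not pass in every fit with 1 array left out, with highest adjusted p-values of 0.104 without db/db replicate 1, 0.0906 without db/m replicate 1, 0.0805 without db/db replicate 3, 0.0877 without db/db replicate 3, 0.0516 without db/m replicate 3, 0.0705 without db/db replicate 1 and 0.0987 without db/m replicate 1.

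**Figure D2:**
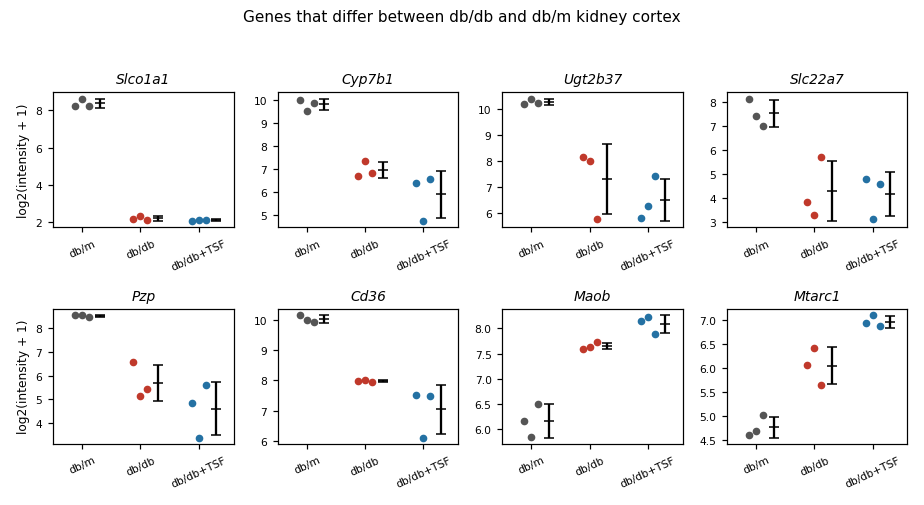
Each panel gives 1 gene, with log2(intensity + 1) on the y axis and the 3 groups on the x axis; points are arrays and black bars the mean ± SD of 3 arrays. Slco1a1 falls from a mean of 8.36 in db/m to 2.21 in db/db, and Maob lies at 6.16 in db/m and 7.65 in db/db.

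In total 187 of 17740 genes passed the threshold, 105 higher and 82 lower in db/db, and 2474 had an unadjusted p under 0.05 where 887 are expected by chance. Of the 187, 8 were at least 2-fold higher and 32 at least 2-fold lower. The groups did not overlap in any of the 187, nor in 18.63% of all genes, against the 10% that chance gives on average with 3 arrays against 3. Genes vary together, so a share well above 10%, or a count above 887, can arise without an effect. Neither was counted on other splits of the arrays. The count was 86, 122 or 109 without db/m replicate 1, 2 or 3, 72, 121 or 82 without db/db replicate 1, 2 or 3, and 116 without db/db+TSF replicate 3. Of the 44 genes past the threshold that the naming rule took, 20 passed in every fit with 1 array left out.

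Of the 22 androgen-raised genes tested, 7 fell, 1 rose and 14 did not pass; adjusted over the list alone, 1 rose and 14 fell. The median was -0.61. Besides Slco1a1, Cyp7b1 and Ugt2b37, Cndp2 (-0.84) and Slc22a28 (-1.16) were among the falls. The list member that rose was Oat (0.53), named after its value was seen. That androgens raise Oat in kidney was not checked here, so its rise is not read as an exception. Of 20 proximal tubule markers, the main cell type of the cortex, only Slc22a7 passed, and the list did not (median -0.03, adjusted p = 0.23).

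Markers of the loop of Henle and distal tubule were higher in db/db. All 15 lay above 0, and 2 rose, Slc8a1 (0.88) and Calb1 (0.68), which serve calcium reabsorption; adjusted over the list alone, 5 rose and 0 fell (adjusted p = 2.9e-06, and adjusted p = 0.083 with an estimated correlation). Slc8a1 and Calb1 did not pass in every fit with 1 array left out (highest adjusted p 0.125 without db/m replicate 1 and 0.155 without db/db replicate 1). Collecting duct markers shifted upward with 0 of 14 past the threshold (adjusted p = 0.00403, and adjusted p = 0.423 with an estimated correlation). Podocyte markers, with 0 of 14 past the threshold, were also higher (adjusted p = 0.0226, and adjusted p = 0.31 with an estimated correlation), and the call was lost without db/m replicate 2 (0.106) or without db/db replicate 3 (0.0542). Nphs1, a gene of the podocyte slit diaphragm, averaged 6.25 in db/m and 6.49 in db/db (adjusted p = 0.298). In the list of mesangial and smooth muscle markers Rgs5 (0.64), a pericyte gene, rose (adjusted p = 0.0181, and adjusted p = 0.352 with an estimated correlation), and the list's call was lost without db/m replicate 2 (0.0887). Rgs5 did not pass in every fit with 1 array left out (highest adjusted p 0.0772 without db/db replicate 3).

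Lymphocyte markers were lower. Of 14 T, B and plasma cell markers 13 lay below 0 and Cd3e, a T cell receptor component, fell by 0.78; adjusted over the list alone, 0 rose and 3 fell (adjusted p = 8.1e-05, and adjusted p = 0.124 with an estimated correlation). Cd3e did not pass in every fit with 1 array left out (highest adjusted p 0.0951 without db/db replicate 1). The chemokine gene Ccl5 fell by 1.16. Of 18 macrophage and dendritic cell markers 16 lay below 0 and 0 passed (adjusted p = 0.00214, and adjusted p = 0.23 with an estimated correlation). Of 24 interferon response genes 23 lay below 0 and 0 passed (adjusted p = 9.5e-04, and adjusted p = 0.606 with an estimated correlation), and the call was lost without db/db replicate 3 (0.296).

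In the other direction, neutrophil markers were higher with 0 of 11 past the threshold (median 0.62, adjusted p = 0.00926, and adjusted p = 0.64 with an estimated correlation). The call was lost without db/db replicate 3 (0.979): S100a8 measured 6.10 in that array and 2.36 and 2.45 in the other db/db arrays. Lcn2, an injury and neutrophil gene, measured 7.88 in the same array and 5.47 and 5.17 in the others (adjusted p = 0.442). The tubular injury list passed with rises of Sprr1a (1.64) and Krt19 (0.49) (adjusted p = 0.0264, and adjusted p = 0.64 with an estimated correlation), and its call was lost without db/m replicate 1 (0.0879), without db/m replicate 2 (0.0887) or without db/db replicate 3 (0.609). Krt19 did not pass in every fit with 1 array left out (highest adjusted p 0.137 without db/m replicate 1). Havcr1, a marker of proximal tubule injury, averaged 3.65 in db/m and 3.49 in db/db (adjusted p = 0.669).

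Of 33 cell cycle genes 29 lay above 0 and Cdc20 (0.56) and Prc1 (0.64), both of mitosis, rose. Adjusted over the list alone, 13 rose and 0 fell (camera adjusted p = 2.2e-07, and adjusted p = 0.352 with an estimated correlation). Cdc20 (3.53 to 3.71 in db/m, 4.05 to 4.28 in db/db) and Prc1 (3.04 to 3.38 and 3.66 to 4.05) were dim. The array medians over all probe sets were 3.50 to 3.61 on the log2 scale. Of 23 genes of glycolysis and glucose transport 20 lay above 0 and the pyruvate kinase gene Pklr (0.69) rose; adjusted over the list alone, 6 rose and 0 fell (adjusted p = 4.3e-05, and adjusted p = 0.23 with an estimated correlation). Gluconeogenesis genes were higher with 0 members past the threshold (adjusted p = 0.00375, and adjusted p = 0.31 with an estimated correlation). The same held for oxidative phosphorylation (adjusted p = 0.0226, and adjusted p = 0.64 with an estimated correlation), whose call was lost without db/m replicate 1 (0.112), without db/m replicate 2 (0.0698), without db/db replicate 1 (0.148) or without db/db replicate 3 (0.135). Among the hypoxia targets Pdk1 rose (adjusted p = 0.00731, and adjusted p = 0.352 with an estimated correlation), and the list's call was lost without db/db replicate 3 (0.2). In the cholesterol synthesis list Cyp51 (-1.94) fell (adjusted p = 0.0259, and adjusted p = 0.352 with an estimated correlation), and the call was lost without db/m replicate 1 (0.0712), without db/m replicate 3 (0.087) or without db/db replicate 3 (0.258). Cdc20, Prc1, Pklr and Cyp51 did not pass in every fit with 1 array left out (highest adjusted p 0.0958 without db/db replicate 1, 0.143 without db/db replicate 1, 0.119 without db/db replicate 3 and 0.0712 without db/m replicate 1).

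The circadian clock list was higher, with Wee1 (0.82) past the threshold; adjusted over the list alone, 9 rose and 2 fell (adjusted p = 9.5e-04, and adjusted p = 0.23 with an estimated correlation). Wee1 did not pass in every fit with 1 array left out (highest adjusted p 0.0536 without db/db replicate 1). Clock genes also differed within db/m: Npas2 measured 7.86 in replicate 3 and 5.73 in replicate 1. A clock phase score, late-night minus daytime clock genes, was chosen after results were seen. It averaged -0.931 in db/m and -1.84 in db/db (SD within groups 0.593), with overlapping groups and 0.038 in db/m replicate 3. Another time of day at collection thus stays open for the clock genes. Adipocyte markers were lower (adjusted p = 0.0181, and adjusted p = 0.533 with an estimated correlation), a call lost without db/m replicate 2 (0.357). Renin-angiotensin and sodium transport genes (adjusted p = 0.0396, and adjusted p = 0.31 with an estimated correlation) and glucocorticoid receptor targets (adjusted p = 0.0264, and adjusted p = 0.647 with an estimated correlation) were higher, each with 0 members past the threshold. The first call was lost without db/m replicate 2 (0.124), without db/m replicate 3 (0.074), without db/db replicate 1 (0.129), without db/db replicate 3 (0.0707), without db/db+TSF replicate 1 (0.0514) or without db/db+TSF replicate 2 (0.0532), and the second without db/m replicate 1 (0.0879) or without db/db replicate 3 (0.81). In all, 20 of 42 lists passed, 14 upward and 6 downward, 11 passed without db/db replicate 3, and 0 passed with an estimated correlation (fry called 7).

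Adjusted p-values of the 22 lists that did not pass ran from 0.0682 to 0.999. Within them the efflux pump genes Abcb1a (0.86) and Abcc4 (0.92), the fatty acid hydroxylase Cyp4a14 (0.89), the elongase Elovl6 (0.63), the lipid carrier Apoe (0.76), the epoxide hydrolase Ephx1 (0.67), Gsta4 (0.62), Prodh2 (0.76) and Tfpi (0.49) rose, while Fmo5 (-1.36), Me1 (-0.85) and Slc22a2 (-0.49) fell. Elovl6, Apoe, Ephx1, Gsta4, Prodh2, Tfpi and Slc22a2 did not pass in every fit with 1 array left out (highest adjusted p 0.149 without db/db replicate 1, 0.0874 without db/m replicate 1, 0.114 without db/db replicate 3, 0.149 without db/db replicate 1, 0.106 without db/m replicate 1, 0.155 without db/db replicate 1 and 0.09 without db/db replicate 3). Abcc4 was named after its value was seen. Lepr, the mutated gene, was dim in all groups, at 3.83 in db/m and 3.96 in db/db (adjusted p = 0.814), and Ucp1, a brown fat gene, was at 3.08 and 2.92 (adjusted p = 0.593).

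The comparison of db/db+TSF with db/db asks what the formula changed in diabetic cortex. No single gene passed, while genes that glucocorticoids raise were higher as a group and androgen-raised genes and macrophage markers were lower as groups, each with an adjusted p of 0.97 with an estimated correlation. Of the 10 ways to split these 6 arrays 3 against 3, 5 gave at least the 6 lists of the real one, itself included. The highest other gave 11, so the number of list calls is no more than other groupings gave. Zbtb16, a zinc-finger transcription factor gene fixed beforehand, averaged 7.51 ± 0.34 in db/m, 6.76 ± 0.39 in db/db and 8.20 ± 0.49 in db/db+TSF (SD, n = 3; limma adjusted p = 0.19 for db/db+TSF against db/db). The order of these averages rests on the group labels as deposited, and exchanged labels between db/db and db/db+TSF are not excluded here. The question arises because published work on this formula, as recalled and not read here, had Zbtb16 lower after treatment, the opposite direction. Whether that result was on RNA or protein, and in which animals, was not checked. Nothing in the labels points to an exchange, and the difference here did not pass. The genes of smallest p, none past the threshold, were Olfr437 (0.83), Rab30 (0.56), Mir99b (0.78), Timm10b (0.61) and Zbtb16 (1.44) on the higher side and Palld (-0.63), Lzts3 (-0.61), Tnfsf15 (-0.78), Serpinb8 (-0.68) and Scube1 (-0.60) on the lower side. A second, dimmer probe set of Timm10b differed by -0.06.

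Limma called 0 of 17740 genes (smallest adjusted p = 0.145), and 2079 had an unadjusted p under 0.05 where 887 are expected by chance; the test without moderation also called 0. The groups did not overlap in 20.11% of genes, against 10% by chance on average. Since genes vary together and other splits were not counted this way, neither excess over chance is evidence of a treatment effect.

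Of 27 glucocorticoid receptor targets 19 lay above 0 and 0 passed; adjusted over the list alone, 5 rose and 0 fell (median 0.22, adjusted p = 5.6e-05, and adjusted p = 0.97 with an estimated correlation). Those of smallest p were Zbtb16 (1.44), Tsc22d3 (0.56), Angptl4 (1.03) and Sgk1 (0.69), none past the threshold over all genes. Because Zbtb16 was chosen in published work on these samples, its part in the list is not independent, and the list was not tested without it. Of 22 androgen-raised genes 18 lay below 0 and 0 passed, with Timd2 (-0.52), Slc22a28 (-0.56) and Cyp7b1 (-1.05) of smallest p (adjusted p = 0.00805, and adjusted p = 0.97 with an estimated correlation). The list's call was lost without db/db replicate 1 (0.0538). Much of the Cyp7b1 difference came from db/db+TSF replicate 2, at 4.74 against 6.40 and 6.58 in the other arrays of that group. Of 18 macrophage and dendritic cell markers 16 lay below 0 and 0 passed, with Lyz2 (-0.80) and Tyrobp (-0.42) of smallest p (adjusted p = 0.0136, and adjusted p = 0.97 with an estimated correlation). Both genes were highest in db/db replicate 3 (6.91 and 6.73), the array with high neutrophil markers. The other db/db arrays had 6.13 and 6.15 for Lyz2 and 6.22 and 6.44 for Tyrobp, still above every db/db+TSF array. Complement and coagulation genes were lower, 16 of 19 below 0 with 0 past the threshold and F3 (-0.47), tissue factor, of smallest p (adjusted p = 0.0315, and adjusted p = 0.97 with an estimated correlation); the call was lost without db/m replicate 3 (0.0739), without db/db replicate 2 (0.0916), without db/db replicate 3 (0.0551) or without db/db+TSF replicate 3 (0.0938).

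Cell cycle genes were lower, with 25 of 33 below 0 and 0 past the threshold (adjusted p = 0.0315, and adjusted p = 0.97 with an estimated correlation), and the call was lost without db/m replicate 3 (0.0739), without db/db replicate 1 (0.0955), without db/db replicate 3 (0.564) or without db/db+TSF replicate 2 (0.619). Neutrophil markers were lower, with 11 of 11 below 0 and 0 past the threshold (adjusted p = 0.0315, and adjusted p = 0.97 with an estimated correlation), and the call was lost without db/m replicate 3 (0.103), without db/db replicate 3 (0.812) or without db/db+TSF replicate 1 (0.174). Their median of -0.66 shrank to -0.0165 without db/db replicate 3, where the test pointed upward, so the shift rests on that array. In all 6 of 42 lists passed with the preset correlation, 3 without db/m replicate 3, and 0 with an estimated correlation or by fry. Extracellular matrix and fibrosis genes (adjusted p = 0.408), tubular injury genes (0.471), chemokines and cytokines (0.778) and autophagy and lysosome genes (0.796) did not pass. Sprr1a averaged 5.77 in db/db and 4.67 in db/db+TSF (adjusted p = 0.237), Lcn2 6.17 and 5.57 (adjusted p = 0.709), and Nphs1 6.49 and 6.63 (adjusted p = 0.58). The direction for Lcn2 rests on db/db replicate 3, at 7.88 against 5.47 and 5.17 in the other db/db arrays. The db/db+TSF arrays measured 6.25, 4.95 and 5.50.

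**Figure D3:**
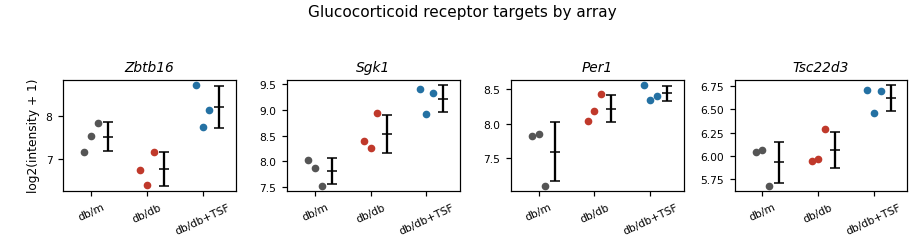
Each panel gives 1 glucocorticoid receptor target, with log2(intensity + 1) on the y axis and the groups on the x axis; points are arrays and black bars the mean ± SD of 3 arrays. Zbtb16 lies between 7.74 and 8.72 in db/db+TSF and between 6.38 and 7.16 in db/db.

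The comparison of db/db+TSF with db/m shows how treated diabetic mice differed from lean mice. The largest falls were Slco1a1 (-6.25), Pzp (-3.90), Cyp7b1 (-3.89), Ugt2b37 (-3.76), Slc22a26 (-3.58), Slc22a7 (-3.36), Alox15 (-3.22), Akr1c14 (-3.22), Cd36 (-2.99) and Slc7a13 (-2.70), of which Slco1a1, Cyp7b1, Ugt2b37 and Slc7a13 belong to the androgen-raised list. The largest rises were Noct (2.26), Mtarc1 (2.20), Maob (1.92), Cyp27b1 (1.77), Bbox1 (1.47), Sgk1 (1.41), Nkain1 (1.39), Rab30 (1.30), Gldc (1.25) and Tchhl1 (1.22). Noct, a gene with a daily rhythm, averaged 5.90 ± 0.38 in db/m and 8.15 ± 0.42 in db/db+TSF, a 4.78-fold difference (SE 0.28, adjusted p = 0.00226). Cyp27b1 makes active vitamin D, and Sgk1 is a kinase gene that corticosteroids raise. Slc22a7, Slc7a13 and Nkain1 did not pass in every fit with 1 array left out (highest adjusted p 0.0557 without db/m replicate 1, 0.101 without db/m replicate 1 and 0.0813 without db/db+TSF replicate 2).

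Of 17740 genes 556 passed, 216 higher and 340 lower, and 3050 had an unadjusted p under 0.05 against 887 by chance. The groups did not overlap in 22.11% of genes, against 10% by chance on average, with the same limit that genes vary together. The count was 220 or 370 without db/m replicate 1 or 2, and 224 or 213 without db/db+TSF replicate 2 or 3. Of the 67 genes past the threshold that the naming rule took, 37 passed in every fit with 1 array left out.

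Of 22 androgen-raised genes 11 fell and 1 rose; adjusted over the list alone, 2 rose and 15 fell (adjusted p = 2.7e-14, and adjusted p = 0.0804 with an estimated correlation). The falls included Cndp2 (-1.06) and Slc22a28 (-1.72), and the list member that rose was again Oat (0.48), whose place on the list was not checked. Of 27 glucocorticoid receptor targets 7 rose, among them Sgk1 (1.41), Mt1 (0.58), Tsc22d3 (0.69) and Per1 (0.85); adjusted over the list alone, 14 rose and 0 fell (adjusted p = 1.7e-07, and adjusted p = 0.361 with an estimated correlation). Of 18 macrophage and dendritic cell markers 7 fell, among them Laptm5 (-0.55), Adgre1 (-0.56), Cd68 (-0.42) and Csf1r (-0.83); adjusted over the list alone, 0 rose and 9 fell (adjusted p = 1.1e-06, and adjusted p = 0.0804 with an estimated correlation). In the list of T, B and plasma cell markers Cd3g (-0.92) and Cd3e (-0.58) fell (adjusted p = 0.0011, and adjusted p = 0.171 with an estimated correlation). Antigen presentation genes (adjusted p = 0.0113, and adjusted p = 0.64 with an estimated correlation) and interferon response genes (adjusted p = 0.00793, and adjusted p = 0.678 with an estimated correlation) were lower with 0 members past the threshold. The first call was lost without db/db+TSF replicate 1 (0.0692), and the second without db/m replicate 1 (0.124) or without db/db+TSF replicate 1 (0.174). Tsc22d3, Per1, Laptm5, Adgre1, Cd68, Csf1r, Cd3g and Cd3e did not pass in every fit with 1 array left out (highest adjusted p 0.088 without db/db+TSF replicate 3, 0.102 without db/db+TSF replicate 3, 0.0703 without db/db+TSF replicate 2, 0.1 without db/db+TSF replicate 3, 0.104 without db/db+TSF replicate 2, 0.102 without db/db+TSF replicate 3, 0.0707 without db/m replicate 1 and 0.169 without db/db+TSF replicate 2).

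Of 15 loop of Henle and distal tubule markers 4 rose, Calb1 (1.04), Slc8a1 (1.12), Trpv5 (0.85) and Pvalb (0.54); adjusted over the list alone, 8 rose and 1 fell (adjusted p = 4.6e-05, and adjusted p = 0.0804 with an estimated correlation). Collecting duct markers were higher with 0 past the threshold (adjusted p = 0.00973, and adjusted p = 0.567 with an estimated correlation), a call lost without db/m replicate 1 (0.0521) or without db/db+TSF replicate 1 (0.0523). In the sodium transport list Sgk1 (1.41) and Scnn1a (0.69) rose and Ace (-1.28) fell (adjusted p = 0.0481, and adjusted p = 0.296 with an estimated correlation), and the call was lost without db/m replicate 2 (0.115), without db/m replicate 3 (0.0645), without db/db replicate 1 (0.0553), without db/db replicate 3 (0.0528) or without db/db+TSF replicate 1 (0.228). The list median of 0.0481 became -0.0242 without db/db+TSF replicate 1. Ace measured 7.66 in db/db+TSF replicate 2 and 9.24 and 8.76 in the other arrays of that group. In the clock list 5 genes rose and 2 fell (camera adjusted p = 5.5e-04, and adjusted p = 0.171 with an estimated correlation). Among them Wee1 (1.22) and Cry1 (1.13) rose and Nr1d1 (-1.26) and Npas2 (-1.98) fell. Another time of day at collection stays open for these genes as well. Trpv5, Pvalb, Scnn1a, Ace, Cry1 and Npas2 did not pass in every fit with 1 array left out (highest adjusted p 0.0541 without db/m replicate 1, 0.0767 without db/m replicate 1, 0.0944 without db/m replicate 1, 0.141 without db/m replicate 3, 0.0568 without db/m replicate 1 and 0.114 without db/db+TSF replicate 3).

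Cholesterol synthesis genes were lower, with falls of Cyp51 (-2.49) and Sqle (-0.81) (adjusted p = 0.00215, and adjusted p = 0.235 with an estimated correlation). All 14 gluconeogenesis genes lay above 0 with 0 past the threshold; adjusted over the list alone, 6 rose and 0 fell (adjusted p = 1.0e-04, and adjusted p = 0.171 with an estimated correlation). Glycolysis and glucose transport genes were higher, with Pklr (0.68) past the threshold (adjusted p = 4.1e-04, and adjusted p = 0.277 with an estimated correlation). Oxidative phosphorylation genes were higher with 0 past the threshold (adjusted p = 0.0113, and adjusted p = 0.64 with an estimated correlation), a call lost without db/m replicate 1 (0.0659). Cell cycle genes were higher, with the dim gene Cdc20 (0.41) past the threshold (camera adjusted p = 0.00351, and adjusted p = 0.64 with an estimated correlation). The list's call was lost without db/m replicate 2 (0.0536). Sqle, Pklr and Cdc20 did not pass in every fit with 1 array left out (highest adjusted p 0.115 without db/db+TSF replicate 2, 0.0752 without db/m replicate 1 and 0.158 without db/db+TSF replicate 3). In all 15 of 42 lists passed, 9 upward and 6 downward, and 0 did with an estimated correlation (fry called 7).

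The same 147 genes passed in both comparisons with db/m, 73 higher and 74 lower in both and 0 in opposite directions; independent lists would share 1.28 and 1.57. These comparisons share the 3 db/m arrays. In 100 simulations of unchanged groups 0 genes were shared, but groups without change leave hardly any genes to call, so this 0 is no comparison for the 147. Across genes, which are not independent replicates, the fold changes had a covariance of 0.0438 against 0.0111 in those simulations, a difference of 0.0327. With the db/m arrays split so that none were shared, 1 for one comparison and 2 for the other, the covariance averaged 0.0311 (0.0284 to 0.0354 over 6 splits, a check chosen after the results were seen). The count of shared genes was not repeated on such splits, which leave fewer than 2 arrays in a part, so part of its excess may come from the shared controls. Another 409 genes passed only in db/db+TSF and 40 only in db/db, and the difference between those comparisons is the comparison of db/db+TSF with db/db, in which limma called 0 genes (2079 at an unadjusted p under 0.05).

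Whether TSF moved expression back toward db/m was asked across genes. Of the 187 genes called between db/db and db/m, 91 lay closer to db/m in db/db+TSF than in db/db and 96 further away; choosing them on the same db/db arrays favours the first, by an amount not simulated here, so the tally gives no measure of a return. Over all genes the TSF effect (db/db+TSF minus db/db) and the db/db effect (db/db minus db/m) had a covariance of -0.0102 (r = -0.233), and sharing the db/db arrays alone gave -0.0111 (r = -0.500). The difference of 9.2e-04 was smaller than its SD over the fits with 1 array left out, 0.00123. It was -0.000499 without db/m replicate 1 and -3.7e-04 without db/db+TSF replicate 2, and 0.00283 and 0.00263 without db/db replicate 3 and db/db+TSF replicate 3. With the db/db arrays split so that none were shared, the mean covariance was 2.3e-04, from single splits of both signs (-0.0044 to 0.00607).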

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

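The test of probe sets outside the gene-level comparisons was chosen after the gene results were seen. Of 1368 probe sets that the array annotation assigns to several genes, which the comparisons leave out, 8 passed limma's threshold in db/db against db/m, 4 higher and 4 lower, and 12 passed in db/db+TSF against db/m, 6 higher and 6 lower; in db/db+TSF against db/db limma called 0 (81 at an unadjusted p under 0.05). Of 8719 probe sets with no gene in the annotation, limma called 0 in db/db against db/m (592 at an unadjusted p under 0.05), 0 in db/db+TSF against db/db (813) and 2 in db/db+TSF against db/m, 1 higher and 1 lower. No other tool was run on these probe sets. Those past the threshold drew attention because they carry a difference between groups that the gene counts omit, and no gene is named from them.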

How the results depend on the processing

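Leaving out 3 arrays together and omitting the pseudocount were chosen after the data were seen; the other alternatives were fixed beforehand. Counted per gene and alternative, 1966 called results for single genes stayed past the threshold in the same direction over the alternatives, 476 no longer passed and 0 reversed; for called lists 746 stayed, 153 no longer passed and 3 reversed. Of those not called, 125 gene and 39 list results passed under an alternative. For db/db against db/m the 187 genes became 92 with 3 arrays left out (db/m replicate 3, db/db replicate 3, db/db+TSF replicate 2), 348 by unadjusted p with a 1.5-fold change, 442 at an adjusted p of 0.1, and 2 (Slco1a1 and Ncbp1, the latter named after its value was seen) in a test without moderation on 2 groups alone; with 1 array left out they ranged from 72 to 194. The 20 lists became 0 with an estimated correlation, 7 with fry and 14 with a filter at the 50th percentile (8 upward), and 11 to 21 with 1 array left out. For db/db+TSF against db/db, where limma called 0 genes, unadjusted p with a 1.5-fold change gave 136. The 6 lists became 3 on arrays rescaled to one median, 3 with 2 groups alone in the fit, 3 with log2(value + 16), 0 with an estimated correlation and 0 with fry, and 3 to 6 with 1 array left out. For db/db+TSF against db/m the 556 genes became 295 with the 3 arrays left out, 337 with a 1.5-fold change besides, 1012 at an adjusted p of 0.1 and 1 (Slco1a1) without moderation, and 213 to 563 with 1 array left out; the 15 lists became 0 with an estimated correlation, 7 with fry and 23 with the 3 arrays left out. The median shift of neutrophil markers in db/db+TSF against db/db was 0.0029 with the 3 arrays left out, and from -0.97 to -0.0165 with 1 array left out, the last, without db/db replicate 3, going with a test in the upward direction; that of cell cycle genes was 0.0012 with the 3 arrays left out. The covariance difference between the TSF and db/db effects was 0.00334 with a filter at the 50th percentile, 0.00289 after quantile normalization, 0.00255 with log2(value + 16), -0.002 with the 3 arrays left out, 0.0916 over genes past the threshold in db/db against db/m (chosen on the same arrays, which the simulation does not copy, so it bears on no return), and -0.000499 to 0.00283 with 1 array left out. A looser or stricter threshold raises or lowers counts by construction, and fewer arrays lower power; the cause of the rises with fewer arrays and of the other changes was not tested. No strong pairing of arrays by replicate number was seen: deviations of same-numbered arrays correlated between -0.0791 and 0.147, and 3 of 9 arrays correlated best with their own number. A weak pairing is not excluded, and the labels do not say whether the numbers pair mice. With the replicate block 137, 0 and 434 genes passed (187, 0 and 556 without). No detection calls were used here, so signal over background limits what can be said of dim genes.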

Other observations

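The tests of proximal tubule cells, of androgen signal, of members varying together and of time of day, the change of the distance on quantile normalization and the setting of its lowest value against an SD were chosen after the results they bear on were seen; the others in this part were written down before.

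Among lists that did not pass in db/db+TSF against db/m, single genes did. Up to 2 of smallest p are given per list. Of the antioxidant genes Ephx1 (0.93) and Gsta4 (0.86), of the xenobiotic genes the efflux pump Abcc4 (1.12), of the LXR targets the cholesterol exporter Abca1 (0.96), of the fatty acid oxidation genes Cyp4a14 (0.99), of the hypoxia targets Pdk1 (0.96), of the catabolism genes Prodh2 (0.85), of the matrix genes Thbs1 (0.46), of the injury genes Clu (0.60), of the pericyte genes Rgs5 (0.60) and of the FOXO genes Foxo3 (0.62) rose. Fmo5, of the smallest p among the xenobiotic genes, fell from a mean of 8.52 in db/m to 7.02 (adjusted p = 0.00101). Of the fatty acid oxidation genes Cyp4a12a (-1.06), of the chemokines Ccl5 (-1.04), of the complement and coagulation genes F3 (-0.55) and C3ar1 (-0.73), of the lipid synthesis genes Me1 (-0.73) and Fads1 (-0.54), of the stress response genes Sdf2l1 (-0.79), and the urate and cation transporters Slc22a12 (-0.80) and Slc22a2 (-0.52) fell. In the lipid synthesis list Elovl6 (0.70), outside the 2 of smallest p and named here after its value was seen, rose. Genes passed in both directions in the catabolism list (2 rose and 4 fell), the LXR list (3 rose and 1 fell) and the list of amino acid and solute transporters (1 rose and 2 fell). Kap, an androgen-raised proximal tubule gene, fell by 1.45. Abca1, Thbs1, Clu, Rgs5, Foxo3, Cyp4a12a, F3, C3ar1, Sdf2l1 and Kap did not pass in every fit with 1 array left out (highest adjusted p 0.0695 without db/db+TSF replicate 2, 0.118 without db/db+TSF replicate 3, 0.134 without db/m replicate 1, 0.0651 without db/db+TSF replicate 2, 0.111 without db/m replicate 1, 0.067 without db/m replicate 1, 0.0518 without db/db+TSF replicate 2, 0.0703 without db/db+TSF replicate 3, 0.0649 without db/db+TSF replicate 3 and 0.0923 without db/m replicate 3).

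Androgen-raised genes were lower in db/db than in db/m, with a median of -0.61 (adjusted p = 0.124 with an estimated correlation). A smaller share of proximal tubule cells as a whole is argued against, since of 18 proximal tubule markers not on that list 17 lay above -0.61 by more than 2 SE, Slc22a7 being the exception (median -0.0061, SD over genes 0.786); a loss of 1 tubule segment was not tested. Nor did a single array carry it, since the largest camera adjusted p with 1 array left out was 7.0e-10. Lower androgen signal may underlie it and stays open: female-biased kidney genes, which it would raise, did not pass as a list (camera adjusted p = 0.247). Of the 11 tested, 7 lay above 0 and 4 below. Cyp4a14 (0.89) and Gsta4 (0.62) rose past the threshold and 0 fell, and adjusted over the list alone 3 rose and 1 fell. Hormone levels were not analysed here.

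Glucocorticoid receptor targets were higher in db/db+TSF than in db/db. No single array carried the call with the preset correlation (largest adjusted p 0.0248, without db/db+TSF replicate 1). The groups overlapped in the mean over the list, at 7.07, 7.04 and 7.57 in the db/db arrays and 7.74, 7.27 and 7.48 in the db/db+TSF arrays. The members varied together within groups (estimated correlation 0.365), and with that estimate the adjusted p was 0.97, so the shift may be no more than variation between mice. Another time of day at collection stays open: the clock phase score was higher by 0.637 in db/db+TSF against an SD within groups of 0.593, with overlapping groups, and the list without Per1, Klf9 and Klf15 had an adjusted p of 2.6e-05 with the preset correlation and adjusted p = 0.97 with an estimated correlation. A treatment effect is the biological explanation the design names, and these arrays leave it open.

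The db/db+TSF group lay further from db/m than db/db did: the mean squared log2 difference with noise removed was 0.0468 against 0.0319, a difference of 0.0149. It stayed above 0 with each array left out, which the test written down before asked, but fell to 0.00448 without db/db+TSF replicate 2, below its SD over those fits (0.00547), so that a single array may account for much of it. Brightness is argued against as the whole cause: quantile normalization, which should remove the difference, raised it to 0.0166, a change of 0.00167 (SD over arrays left out 5.7e-04) and upward with each array left out. The bound written down before, the width of the range with 1 array left out (0.0191), was not exceeded by the 0.0166. Fits with 1 array left out share most of their arrays, so the SD over them is not a sampling error. Brightness is thus argued against for these arrays only. An exact two-sided permutation of the 6 arrays of db/db and db/db+TSF gave p = 0.3, but 0.1 is the smallest it can give and it does not bear on exchanged labels, so chance between mice, exchanged labels and a treatment effect all stay open.

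With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For db/db against db/m, 1 of the 10 splits gave as many genes, the real one with 187 and the highest other with 1, and 1 gave as many lists, with 20 and 14. For db/db+TSF against db/db the real count was 0 genes with limma (2079 at an unadjusted p under 0.05, and 0 without moderation). All 10 splits reach 0 by construction, so the tally of genes decides nothing there. The highest other split gave 1 gene, and 5 of the 10 gave as many lists, with 6 and 11. For db/db+TSF against db/m, 1 gave as many genes, with 556 and 0, and 1 as many lists, with 15 and 11.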
